A study of Homo sapiens with 36 samples.

How the data were processed

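RNA sequencing was done on A549 cells, a human lung adenocarcinoma line. Per the labels, cells were transfected with a non-targeting siRNA (siControl) or with siRNA against ATF4 or ATF6 at 100 nM. Each transfected culture was then divided over wells and kept in medium with 25 mM glucose or without glucose (0 mM) for 6 or 16 h, with 10% dialysed serum and 2 mM glutamine in both. The 12 combinations of siRNA, glucose and time hold 3 biological replicates each, which makes 36 libraries. The libraries were poly(A)-enriched, not stranded and read as pairs of 150 bases. The submitters' notes name fastp, STAR and RSEM with the GRCh38 genome, without versions. The annotation release is not given in the sources used here, and positions of genes are those of the deposited table.

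The deposited table holds expected counts from RSEM for 60662 gene IDs, one column for each library, as produced by the authors. Expected counts were rounded to whole numbers, and columns were matched to libraries through the column names in the labels. All columns were used. Totals ran from 39.4 to 78.7 M counts in 35 libraries. The remaining library, siATF4 in 0 mM glucose at 6 h, replicate 3, held 2.87 M. For any pair of replicates the mean chi-square per gene was at least 9.90, where counting noise alone gives 1, so the spread between cultures rather than depth set the precision for expressed genes.

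Genes were tested with edgeR 4.0.16 in R 4.3.3. The steps were filterByExpr by group (minimum count 10, minimum total 15), TMM factors, quasi-likelihood fits with robust dispersion, and F tests, with Benjamini-Hochberg adjustment across all genes within each comparison at 0.05. One mean was fitted per group, without covariates. The design and its 21 comparisons were set before the data were examined, as were the gene lists, the rule for naming genes and the alternative settings. They comprise the effect of deprivation within each siRNA and time, each knockdown against siControl within each glucose concentration and time, the interactions of deprivation with siRNA, and the interaction of deprivation with time in siControl. P-values of genes rest on the pooled spread of cultures of 1 cell line.

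The planned fit used all 36 libraries (18733 IDs tested). After the data were seen, 3 further fits were added. They leave out the library with 2.87 M counts (35 libraries, 19030 IDs), leave out that library and all 6 h libraries of replicate 2 (29 libraries, 19644 IDs), or use the 18 libraries of 16 h alone (18013 IDs). No library was moved to another group.

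Gene lists were tested against all other genes with camera in limma 3.58.1. The correlation between genes was preset at 0.01 or estimated. P-values were adjusted over the lists of a comparison. Fry was an alternative. The 32 lists, written from general knowledge, cover ER chaperones and folding enzymes, ER-associated degradation and signalling of the unfolded protein response, ER translocation and secretory transport, stress regulators downstream of ATF4, amino acid synthesis and one-carbon enzymes, amino acid transporters and aminoacyl-tRNA synthetases. Others cover glycolysis, the hexosamine pathway, MondoA targets, cholesterol synthesis and efflux, fatty acid synthesis, respiratory chain subunits, mitochondrial mRNAs, S phase, mitosis, histones, ribosomes and their biogenesis, immediate early genes, p53 targets, death receptors, lysosome, NRF2, hypoxia, heat shock, NF-kB and interferon genes, cytokines, matrix genes and markers of non-epithelial cells. List members past 0.05 are counted over all genes tested and adjusted over the list alone.

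The rule for named genes took, in each comparison, up to 6 genes per direction with the largest change past 0.05, a mean of at least 5 CPM in one of the groups, and the same direction in every pair of replicates with the same number (this last condition does not apply to interactions). Of each list, the 2 to 4 members with the smallest adjusted p were named, with members past 0.05 in the opposite direction. Values per group are CPM, mean ± SD; log2 fold changes are those of the edgeR fits. Exons that overlap another gene were found in a reference annotation, since reads that are not stranded cannot be assigned between overlapping genes.

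Alternatives were DESeq2 1.42.0, size factors by the median-of-ratios method, upper-quartile factors, no filter on low counts, only the libraries of the groups compared, each library left out in turn, and the replicate number or the transfection as a block. Genes that changed by at least 1 on the log2 scale in siControl were followed in the knockdowns, and 10 data sets without an interaction were simulated for comparison. The pipeline was tested on simulated data with 200 changed genes. In the 16 h libraries alone, the deprivation test in siControl recovered 11.9% of genes set to change 1.5-fold, 58.2% of those at 2-fold and 84.8% of those at 4-fold. The interaction with siATF4 recovered 1.49%, 14.9% and 69.7%. In the planned fit the deprivation test recovered 0, 2.99% and 21.2%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.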

Results

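ATF4, the transcription factor through which the integrated stress response turns on amino acid synthesis and transport, and ATF6, a membrane-bound factor of the unfolded protein response that turns on chaperones of the endoplasmic reticulum (ER), were each silenced in A549 cells before glucose was withdrawn. At 16 h in siControl cells, ATF4 mRNA stood at 158 ± 19.5 CPM in 25 mM glucose and at 460 ± 36.3 CPM in 0 mM (SD, n = 3). ATF6 mRNA stood at 45.5 ± 0.621 and 91.0 ± 0.816 CPM. Both rose with deprivation, by 1.54 (adjusted p = 9.99e-07) and 1.00 (adjusted p = 0.000427) on the log2 scale in edgeR. With siATF4, ATF4 was 130 ± 10.5 CPM in 25 mM glucose, a difference from siControl of -0.28 that missed the threshold (adjusted p = 0.759). In 0 mM it was 190 ± 33.2 CPM, lower by a log2 fold change of -1.29 (adjusted p = 0.000186). With siATF6, ATF6 was 8.84 ± 1.29 and 15.4 ± 4.99 CPM, with log2 fold changes of -2.36 (adjusted p = 1.79e-05) and -2.58 (adjusted p = 4.85e-06). At 6 h ATF6 was lowered to a similar degree, by -2.30 (adjusted p = 1.39e-05) and -2.17 (adjusted p = 4.55e-05) in edgeR. ATF4 under siATF4 was 154 ± 44.6 CPM against 341 ± 35.2 in 25 mM glucose (-1.15, not past the threshold in edgeR) and 164 ± 67.1 (n = 2) against 355 ± 131 in 0 mM (-1.11, adjusted p = 0.252). Each siRNA left the other factor's mRNA without a change past the threshold at 16 h. ATF4 under siATF6 differed from siControl by 0.38 (adjusted p = 0.298) and 0.31 (adjusted p = 0.248), and ATF6 under siATF4 by 0.11 (adjusted p = 0.984) and -0.44 (adjusted p = 0.0959).

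Fits that leave out doubtful libraries were chosen after the data were seen and lead the parts below, with counts from the planned fit of all 36 libraries beside them. They are the 18 libraries of 16 h alone, 29 libraries without the failed one and 6 h replicate 2 for the deprivation response at 6 h and its change over time, and 35 libraries with replicate 2 kept for the knockdowns at 6 h. With all 36 libraries no list passed with an estimated correlation (lowest adjusted p = 0.116), so each list below that passes with an estimated correlation does so only in these later fits. The library labelled siATF4, 0 mM glucose, 6 h, replicate 3 held 2.87 M counts. Its highest correlation with any other library was 0.151, against a lowest median of 0.945 among the other 35. The libraries labelled replicate 2 at 6 h in siControl and siATF6 moved against their glucose labels. Across 1939 genes changed at 16 h, the log2 ratio of 0 over 25 mM glucose in siControl correlated with the 16 h change at 0.689 and 0.649 in replicates 1 and 3 and at -0.694 in replicate 2. In siATF6 the values were 0.635, 0.564 and -0.639. In siATF4 replicates 1 and 2 gave 0.648 and 0.577. These correlations run across genes, which are not independent replicates. In siControl and siATF6, replicate 2 was thus left out for the direction of its deprivation response, the same quantity that the 6 h tests measure, so their p-values depend on that choice and do not allow for it. In siATF4 it ran with its labels and was left out only along with the others, which leaves 1 library in 0 mM glucose.

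**Figure D1:**
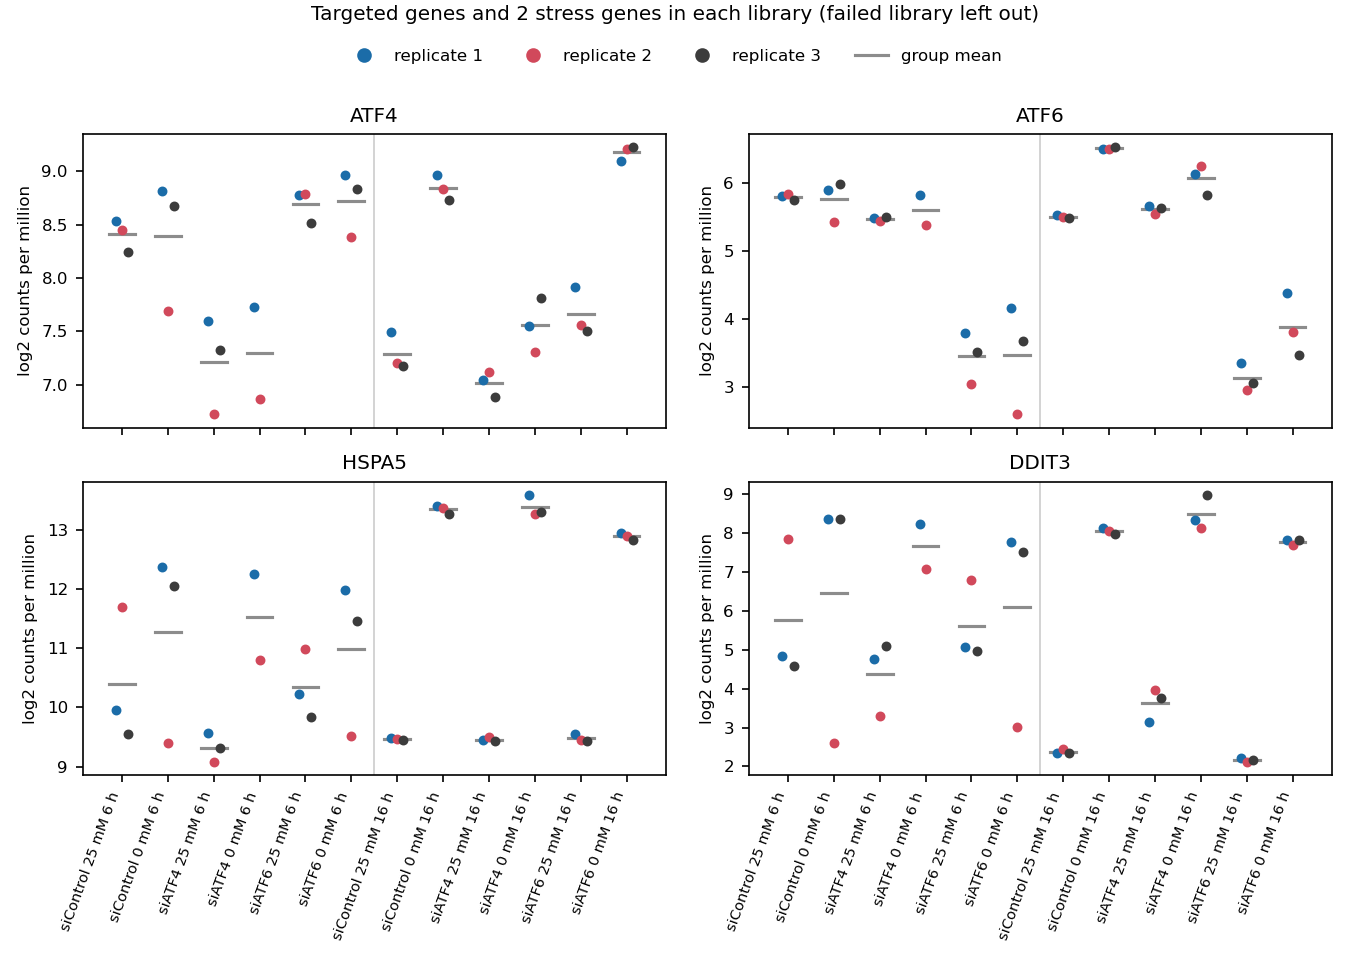
Expression of ATF4, ATF6, HSPA5 and DDIT3 in each library (log2 CPM, vertical axis) by group of siRNA and glucose, with 6 h on the left and 16 h on the right of the grey line. Each point is 1 library coloured by replicate number, grey bars are group means, and the library with 2.87 M counts is left out.

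**Figure D2:**
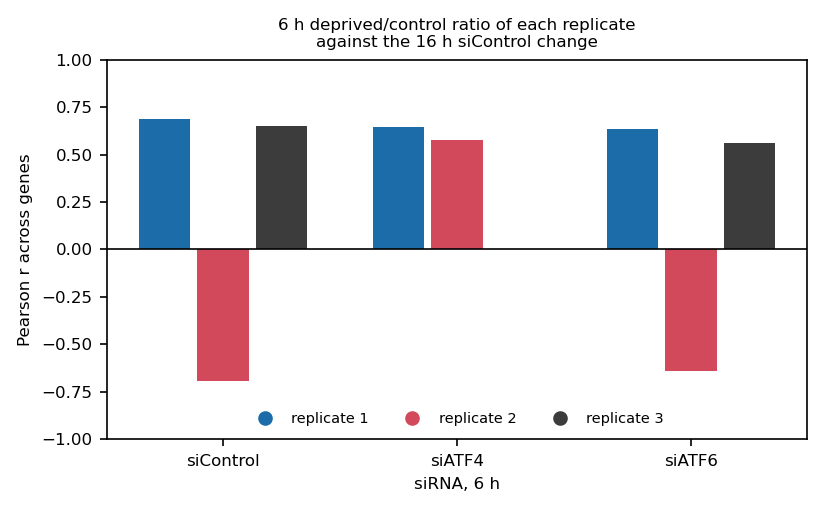
Pearson correlation, across 1939 genes, of each 6 h replicate's log2 ratio (0 over 25 mM glucose) with the change of siControl at 16 h. Each bar is 1 pair of libraries with the same siRNA and replicate number, and bars below 0 run against their glucose labels.

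After 16 h without glucose, siControl cells had raised the ER stress genes together. All 20 measured ER chaperones and folding enzymes rose (adjusted p = 9.06e-06 with an estimated correlation), among them HSPA5, the main HSP70 of the ER lumen (3.88), its co-chaperones DNAJB11 (2.52, from 55.2 ± 0.872 to 317 ± 8.11 CPM) and HYOU1 (3.68), and the secreted stress marker CRELD2 (4.18). Of 19 genes of ER-associated degradation and unfolded protein signalling, 15 rose and 4 did not pass the test (adjusted p = 7.83e-06 with an estimated correlation), led by HERPUD1, a membrane component of the degradation machinery (3.97), the ubiquitin ligase SYVN1 (2.38), the transcription factor XBP1 (2.00) and SELENOS (1.95). Of 25 genes of ER translocation, glycosylation and secretory transport, 22 rose over all genes and 23 adjusted over the list alone (adjusted p = 0.000758 with an estimated correlation), such as the oligosaccharyltransferase subunit OSTC (1.33), the translocon subunit SEC61A1 (1.16), and the signal peptidase subunits SPCS2 (1.23) and SEC11C (1.62).

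The genes that ATF4 is known to drive rose in the same cells. Of 19 stress regulators 18 rose, including DDIT3, which encodes the pro-apoptotic factor CHOP (5.68, from 5.08 ± 0.188 to 261 ± 13.4 CPM), CEBPG (1.71), TRIB3 (3.17) and ATF3 (4.41), while ATF5 fell by 0.87 (list adjusted p = 0.000117 with an estimated correlation). Exons of DDIT3 overlap those of MARS on the other strand over 27.2% of their length, which leaves its exact level uncertain. Of 15 enzymes of amino acid synthesis and one-carbon metabolism 14 rose, such as the mitochondrial folate enzyme MTHFD2 (2.09), the transaminases GOT1 (2.33) and GPT2 (0.97) and asparagine synthetase ASNS (1.43), while ALDH18A1 of proline synthesis fell by 0.31 (adjusted p = 8.19e-05 with an estimated correlation). Of 11 amino acid transporters 9 rose and 2 did not pass, led by SLC1A4 (1.82), SLC6A9 (1.61) and SLC3A2 (1.36; adjusted p = 0.00224 with an estimated correlation). Of 18 aminoacyl-tRNA synthetases, which charge tRNAs for translation, 12 rose (13 adjusted over the list alone), among them WARS1 (2.22), GARS1 (1.81) and CARS1 (1.66), and RARS1 (-0.60) and HARS1 (-0.41) fell (adjusted p = 0.0104 with an estimated correlation).

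Genes of DNA replication fell. Of 22 S phase genes 19 fell, with the replicative helicase subunits MCM3 (-1.95), MCM6 (-2.35) and MCM7 (-2.03) and the ribonucleotide reductase subunit RRM2 (-2.04) at the head of the list (adjusted p = 0.000758 with an estimated correlation). Of 23 genes of G2 and mitosis 21 fell (22 adjusted over the list alone), such as CCNA2 (-1.73) and CDK1 (-1.39). This list call is lost with an estimated correlation (adjusted p = 0.138). Immediate early genes went up, 14 of 16 over all genes and all 16 adjusted over the list alone, for example the MAP kinase phosphatases DUSP5 (1.58) and DUSP1 (1.47; adjusted p = 0.213 with an estimated correlation). Of 24 lysosome and autophagy genes 14 rose (15 adjusted over the list alone), such as WIPI1 (2.63), CTSL (1.24), SQSTM1 (1.31) and MAP1LC3B (2.20; adjusted p = 0.164 with an estimated correlation, 0.0317 with the replicate number as a block too). Of 8 hexosamine pathway genes 5 rose, led by GFPT1, the entry enzyme of the pathway (2.06; adjusted p = 0.202 with an estimated correlation).

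Metabolic and survival genes moved in both directions. In the glycolysis list HK2 (2.82), SLC2A1 (0.61) and SLC2A3 (0.70) rose and 6 of 20 members fell (10 adjusted over the list alone), among them LDHA (-1.05) and PKM (-0.67). The list as a whole did not pass (adjusted p = 0.0544; adjusted p = 0.412 with an estimated correlation). Of 13 SREBP1 targets of fatty acid synthesis 3 fell, FADS2 (-1.02) and FASN (-0.87) with the smallest p, and ME1 rose by 0.26 (adjusted p = 0.0273; adjusted p = 0.432 with an estimated correlation). Among 20 death receptors and BCL2 family members 7 rose, including the TRAIL receptor TNFRSF10B (1.47) and the BH3-only genes HRK (2.74) and BBC3 (1.58), and TNFRSF1A fell (adjusted p = 0.0133; adjusted p = 0.3 with an estimated correlation, 0.0369 with the replicate block too). The NRF2 list, with 8 of 20 up and HMOX1 at 2.41, the hypoxia list, with 8 of 18 up, such as NDRG1 (1.83) and VEGFA (2.04), and 4 down, such as EGLN1 (-0.83), and the ribosomal proteins, with 4 of 20 up, also passed only with the preset correlation (adjusted p = 0.33, 0.396 and 0.685 with an estimated correlation), and NRF2 not with the replicate block (0.0977).

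**Figure D3:**
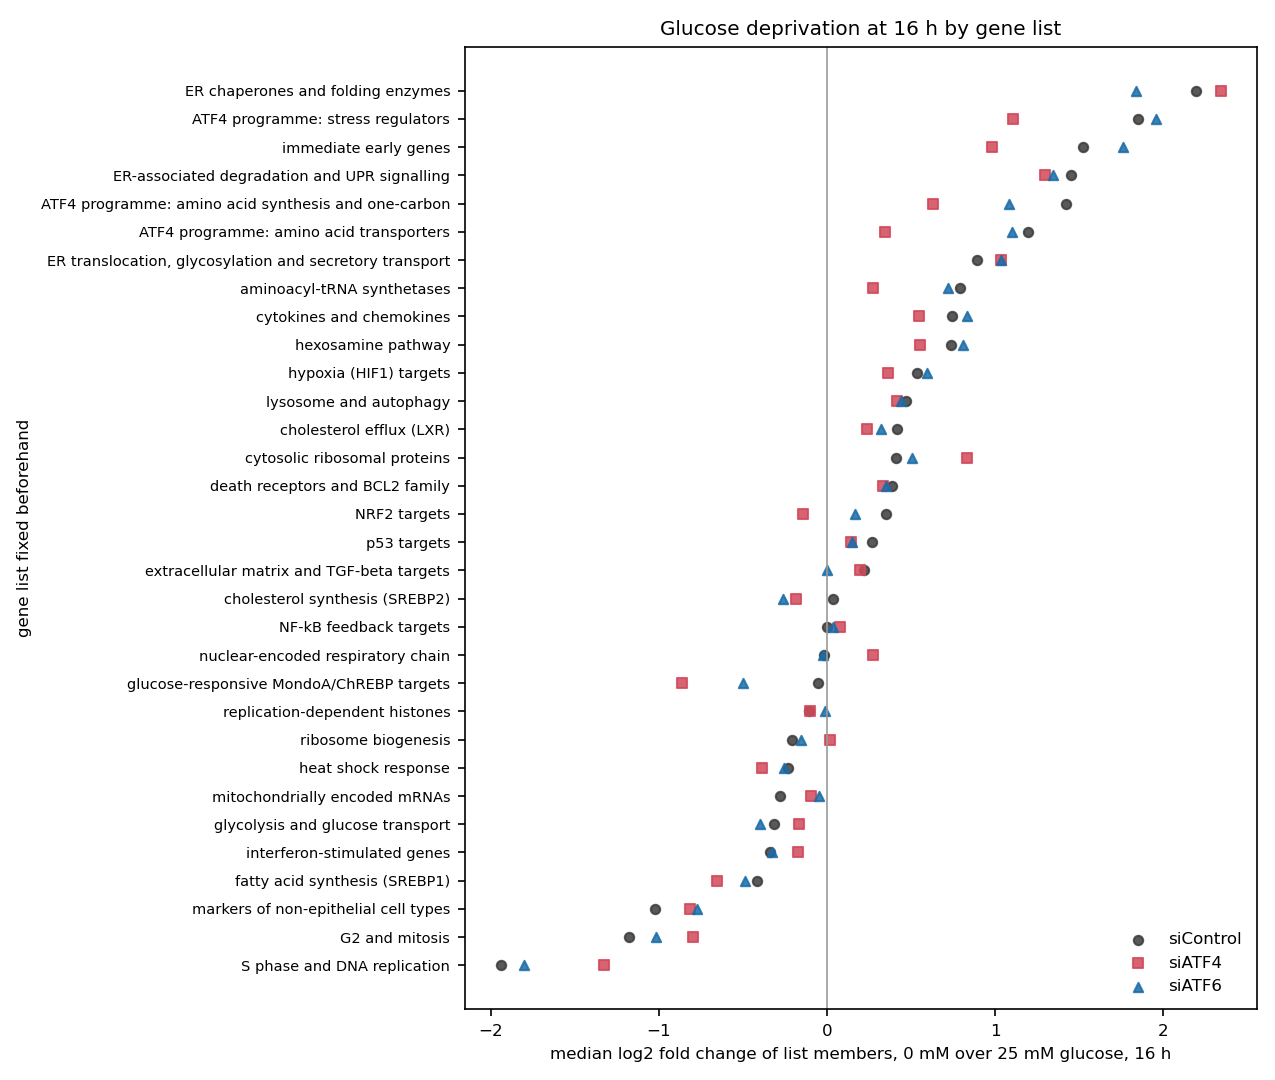
Median log2 fold change (0 over 25 mM glucose at 16 h, horizontal axis) of the measured members of each gene list, for siControl (circles), siATF4 (squares) and siATF6 (triangles).

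Single genes with the largest changes in siControl at 16 h included the inducible HSP70 gene HSPA6 (8.83, but 455 ± 491 CPM in 0 mM glucose), the cadherin CDH15 (7.37, adjusted p = 1.94e-08), the immediate early genes FOSB (6.60) and EGR1, and KLHDC7B (5.93). SFT2D3 had no counts in 25 mM glucose and was at least 324-fold higher in 0 mM against a floor of 3 counts over the group. Its exons lie wholly inside those of WDR33 on the other strand, so the reads cannot be assigned. The largest decreases were in FAM111B (-4.32), NCALD (-3.52), RNF43 (-3.50), CLDN2 (-3.48), E2F2 (-3.19) and NES (-3.11). A share of 57.6% of the exon length of RNF43 belongs also to another annotated gene on the same strand. In all, 5229 of 18013 genes passed in the 16 h libraries (2626 up, 2603 down), against 531 with all 36 libraries (295 up, 236 down).

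The ER stress genes rose in both knockdowns as well, and the knockdowns parted in the ATF4 lists. All 20 ER chaperones rose in siATF4 and in siATF6 cells (adjusted p = 2.48e-06 and 8.28e-05 with an estimated correlation), with HSPA5 at 3.91 and 3.38 and DNAJB11 at 2.64 and 1.85. In the degradation list 16 and 17 of 19 rose (adjusted p = 2.7e-06 and 1.62e-05 with an estimated correlation). In the translocation list it was 22 and 23 of 25 (adjusted p = 0.000224 and 0.000622 with an estimated correlation). Of the stress regulators 13 of 19 rose in siATF4 and 18 in siATF6, with ATF5 down in both (-1.26 and -0.68; adjusted p = 0.00747 and 0.000122 with an estimated correlation). Of the amino acid synthesis genes 7 of 15 rose in siATF4, while PSAT1 (-0.40) and GPT2 (-0.30) fell (adjusted p = 0.0122; adjusted p = 0.157 with an estimated correlation). In siATF6 14 rose (adjusted p = 0.000141 with an estimated correlation). The transporters gave 4 and 9 of 11 up (adjusted p = 0.249 and 1.57e-07; with an estimated correlation the second was at adjusted p = 0.00689, and at 0.0695 with the transfection as a block). The tRNA synthetases gave 8 and 11 of 18 up with RARS1 down in both (adjusted p = 0.21 and 0.0238 with an estimated correlation). S phase genes fell in both, 20 of 22 each (adjusted p = 0.00822 and 0.00153 with an estimated correlation), and cytosolic ribosomal proteins rose in siATF4, 20 of 20, with RPL3 at 1.08 (adjusted p = 7.11e-09; adjusted p = 0.404 with an estimated correlation; 1.1e-06 and 0.441 without siATF4, 0 mM, replicate 3, a library that stood apart). In all, 5233 genes passed in siATF4 (2678 up, 2555 down) and 6033 in siATF6 (2811 up, 3222 down). All 36 libraries gave 325 (148 up, 177 down; 246 up and 173 down with median-of-ratios size factors) and 831 (394 up, 437 down). With only the 6 libraries compared, siATF4 gave 1225.

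The test of the difference in deprivation response between siATF4 and siControl at 16 h picked out the ATF4 lists. The response was lower in siATF4 for 4 of 15 amino acid synthesis genes over all genes and 10 adjusted over the list alone (adjusted p = 2.06e-05 with an estimated correlation), such as GPT2 (-1.27), MTHFD2 (-1.41) and PSAT1 (-1.19). It was lower for 3 of 11 transporters (7 adjusted over the list alone; adjusted p = 0.000324 with an estimated correlation), SLC1A4 (-1.47), SLC1A5 (-0.97) and SLC6A9 (-1.03), and for 2 of 19 stress regulators (12 adjusted over the list alone; adjusted p = 0.000472 with an estimated correlation), CEBPG (-0.71) and DDIT4 (-1.31). Among tRNA synthetases CARS1 (-1.02) and GARS1 (-1.02) passed and 10 of 18 did adjusted over the list alone (adjusted p = 0.0776 with an estimated correlation). Across all genes 31 passed, 2 with a higher response, the WNT inhibitor DKK1 (1.39) and RECQL4 (0.83), and 29 with a lower one. Among the latter the largest values were in the peptide hormone ADM2 (-2.68), KLHDC7B (-2.61), PRDM16 (-2.41), the NKG2D ligand ULBP1 (-2.39, adjusted p = 0.000345) and PTPDC1 (-1.64). ATF4 itself missed the threshold (-1.01, adjusted p = 0.057). With all 36 libraries no gene passed in edgeR (211 at an unadjusted p under 0.05; 93 in DESeq2), with the 35 libraries without the failed one 3 did, and with 29 libraries 62 did. In the 16 h libraries DESeq2 gave 200 and a fit of only the 12 libraries compared gave 6, and 12 genes passed with the transfection and 143 with the replicate number as a block. Leaving out 1 library moved the 31 to 16, 12 and 11 (siControl, 25 mM, replicates 1 to 3), 20 and 15 (siControl, 0 mM, replicates 1 and 3), 17 (siATF4, 25 mM, replicate 3) and 50 each (siATF4, 0 mM, replicates 1 and 3).

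For siATF6 the same test singled out the ER chaperones. No single gene passed in edgeR with the 16 h libraries (412 at an unadjusted p under 0.05; 16 in DESeq2), 7 did with only the libraries compared, 2 with the replicate number as a block, and 1 did without siControl, 0 mM, replicate 1 or replicate 3. All 36 libraries also gave 0 (62; 62 in DESeq2). As a list the ER chaperones responded less in siATF6 than in siControl (adjusted p = 0.0162 with an estimated correlation; with all 36 libraries adjusted p = 0.0741 with the preset correlation and 0.991 with an estimated one), with 7 of 20 passing adjusted over the list alone, and DNAJB11 (-0.68, adjusted p = 0.093) and CRELD2 (-1.11, adjusted p = 0.349) had the smallest p. Set directly against each other, siATF4 cells responded more than siATF6 cells in the ER chaperones (6 of 20 over all genes and 13 adjusted over the list alone; adjusted p = 0.00436 with an estimated correlation), such as CRELD2 (1.68), DNAJB11 (0.79) and PDIA4 (1.33). They responded less in the stress regulators (5 of 19, and 14 adjusted over the list alone; adjusted p = 0.000159 with an estimated correlation), such as DDIT4 (-1.73) and ATF3 (-2.14), in amino acid synthesis (3 of 15 and 9; adjusted p = 5.43e-05 with an estimated correlation) and in transporters (2 of 11 and 7; adjusted p = 0.000805 with an estimated correlation). Across all genes 64 differed (27 up, 37 down). EdgeR gave 0 with all 36 libraries (211 at an unadjusted p under 0.05; 107 in DESeq2), 11 with 35 and 135 with 29. DESeq2 on the 16 h libraries gave 298, no filter 41, only the libraries compared 11, the transfection as a block 21 and the replicate number 218. Without 1 library the 64 became 21 (siATF4, 25 mM, replicate 3), 30, 20 and 37 (siATF6, 25 mM, replicates 1 to 3) and 27 and 28 (siATF6, 0 mM, replicates 2 and 3).

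In 0 mM glucose at 16 h, siATF4 cells held less of the amino acid genes than siControl cells. Of 15 synthesis genes 10 were lower (11 adjusted over the list alone), led by GPT2 (-1.27), the serine synthesis enzymes PSAT1 (-1.59) and PHGDH (-1.39) and MTHFD2 (-0.99), and ALDH18A1 was higher by 0.29 (adjusted p = 0.000107 with an estimated correlation). Of 11 transporters 8 were lower, such as SLC1A4 (-1.35), SLC6A9 (-1.02), SLC1A5 (-0.84) and the cystine importer SLC7A11 (-1.42; adjusted p = 0.00232 with an estimated correlation). Of 19 stress regulators 8 were lower (10 adjusted over the list alone), including DDIT4 (-1.37), VLDLR (-1.25), VEGFA (-1.02) and CHAC1 (-1.84; adjusted p = 1.32e-06; adjusted p = 0.108 with an estimated correlation). Higher in siATF4 were 11 of 20 ribosome biogenesis genes (15 adjusted over the list alone), such as DKC1 (0.75), NOP56 (0.90) and BOP1 (1.04), 11 of 20 ribosomal proteins, 8 of 22 S phase genes, such as MCM7 (0.87) and TYMS (0.96), and 6 of 23 mitotic genes, such as AURKB (1.17) and CDC20 (1.32). Each of these calls is lost with an estimated correlation (adjusted p = 0.174, 0.51, 0.323 and 0.579). The largest single differences were lower LAMP3 (-2.52), PLEKHH2 (-2.47), PRDM16 (-2.27), RPS6KA2 (-2.12), UNC5B (-1.95) and NMNAT2 (-1.89), and higher CCN5 (1.62), ANKRD2 (1.71), DHRS2 (1.75) and HES7 (1.53). EIF3CL (3.25) and THSD8 (1.93) were higher too, but EIF3CL is a near-identical copy of EIF3C and 63.5% of the exon length of THSD8 is shared with RNASEH2A.

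That comparison counted 2235 genes (1318 up, 917 down; with upper-quartile factors 974 up and 1016 down). The library labelled siATF4, 0 mM, 16 h, replicate 3 stood apart at 21303 genes above 0 and 14.4% of counts in its top 20 genes. Without it 912 genes passed; without siATF4 replicates 1 or 2, 3439 or 4029; and without siControl replicates 1, 2 or 3, 1093, 1166 or 543. Only the 6 libraries compared gave 0 in edgeR. All 36 gave 14 (0 up, 14 down; 3 up and 11 down with median-of-ratios factors, 3 up and 21 down with upper-quartile factors), DESeq2 on the 16 h libraries gave 3658 and no filter 1452. The fit of 29 libraries gave 3493.

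In 25 mM glucose the siATF4 difference at 16 h was small. DDIT3 (1.28, from 5.08 ± 0.188 to 12.4 ± 3.35 CPM; adjusted p = 0.0397), CEBPG (0.51), NEFL (0.98) and MARCHF4 (0.72) were higher, and PLA2G4A (-1.03), SEMA3A (-1.03) and MACROH2A1 (-0.63) lower, among 8 genes (4 up, 4 down). MACROH2A1 shares part of its exon length with C5orf66 on the other strand. The stress regulators, with 2 of 19 up and 4 adjusted over the list alone, were higher as a list (adjusted p = 0.0297 with an estimated correlation), as were the tRNA synthetases, with 0 of 18 over all genes and 10 adjusted over the list alone (AARS1 0.70, adjusted p = 0.101; list adjusted p = 0.0428 with an estimated correlation), and the p53 targets, with no member past the threshold (adjusted p = 0.0428 with an estimated correlation, 0.0927 with the replicate block too). Leaving out 1 library moved the 8 to 3, 2 and 2 (siControl replicates 1 to 3) and to 2 and 2 (siATF4 replicates 2 and 3). Only the 6 libraries compared gave 0 (edgeR), DESeq2 165, the replicate block 38, the 35 libraries 1, the 29 libraries 13, and all 36 libraries 0 (150 at an unadjusted p under 0.05; 65 in DESeq2).

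With siATF6 in 0 mM glucose at 16 h, ER chaperones were lower than in siControl. Of 20 members 8 fell over all genes and 12 adjusted over the list alone, such as DNAJB11 (-0.76), CRELD2 (-1.38), the disulfide isomerase PDIA4 (-1.10) and HSP90B1 (-0.90; list adjusted p = 1.35e-12; adjusted p = 0.0981 with an estimated correlation, 0.0205 with the replicate block too). Of the degradation list OS9 (-0.54), DERL3 (-1.95) and SEL1L (-1.05) fell and the list as a whole did not pass (adjusted p = 0.992). A share of 77.0% of the exon length of DERL3 overlaps SMARCB1 on the other strand. In the translocation list SSR3 (0.58) and SEC61A1 (0.41) were higher (5 adjusted over the list alone; adjusted p = 0.00249; adjusted p = 0.445 with an estimated correlation). COL1A1 (-1.20) and CD14 (-1.58), 2 of the 10 measured markers of non-epithelial cells, were lower in the same comparison (adjusted p = 0.0148; adjusted p = 0.271 with an estimated correlation). The largest differences were lower SLC4A8 (-2.48), SYT11 (-2.25), CACNG4 (-1.90) and GPC6 (-1.85). Higher were KRT15 (1.31), FST (1.22), H2AC6 (1.00), NFKB2 (0.96), TMEM189-UBE2V1 (0.95) and ISG20 (0.94). The readthrough gene TMEM189-UBE2V1 shares 74.9% of its exon length with UBE2V1.

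In 25 mM glucose siATF6 lowered NKAIN4 (-2.16), GPC6 (-1.89), CDH4 (-1.88, adjusted p = 2.35e-05), SLC4A8 (-1.81) and SDK2 (-1.78). It raised SQSTM1 (0.80), IPPK (0.79), NFKB2 (0.78), ADAMTSL4 (0.78), ASNS (0.73) and POLR3G (0.69). Exons overlap those of another gene over 72.0% of the length of IPPK, 44.6% of ASNS and 20.7% of SQSTM1. The 19 matrix genes were lower as a list only with the preset correlation (5 members adjusted over the list alone; adjusted p = 6.73e-05; adjusted p = 0.605 with an estimated correlation). COL1A1 (-1.29) fell among the markers of non-epithelial cells (adjusted p = 0.00384, and 0.12 with an estimated correlation).

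These siATF6 comparisons counted 725 genes in 0 mM (200 up, 525 down) and 135 in 25 mM (34 up, 101 down; with upper-quartile factors 23 up and 138 down), against 10 (1 up, 9 down) and 4 (1 up, 3 down) with all 36 libraries. Without 1 library the 725 became 376 and 252 (siControl replicates 2 and 3) and 279 and 207 (siATF6 replicates 2 and 3). The 135 became 36 and 23 (siControl replicates 2 and 3) and 54, 19 and 36 (siATF6 replicates 1 to 3). DESeq2 gave 1542 and 490, no filter 448 and 77, the replicate block 1836 and 531, and only the libraries compared 942 in 25 mM. The fit of 29 libraries gave 1100 and 244.

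Genes that siControl changed by at least 1 on the log2 scale at 16 h were followed in the knockdowns. The 1013 induced genes had a median of 1.47 in siControl, 1.11 in siATF4 (SD over replicate pairs 0.144) and 1.42 in siATF6 (SD 0.109). In 10 simulations without an interaction the median in a second group was 1.29, since genes chosen for a high value in siControl fall back, and with 1.28 simulated for siATF6 both gaps are little more than the SD. With all 36 libraries 239 induced genes gave 1.36 in siATF4 and 2.05 in siATF6, against 1.36 and 1.34 simulated. There a lower median in siATF4 is not shown and siATF6 lay above by more than its SD of 0.158, but the simulations held 505 induced genes on average. Of the 1013 genes 23 passed the interaction test in siATF4 (2.27%, 0 in the simulations), and 0 passed in siATF6. Chance stays open for siATF4: 6 of 25 splits, the real one included, gave at least 31 genes, but some keep its effect in 0 mM. The 926 reduced genes had medians of -1.43 in siControl, -1.18 in siATF4 (SD 0.103) and -1.52 in siATF6 (SD 0.0233), against -1.28 and -1.27 simulated, and 1 passed the interaction test in siATF4. Reduced genes in siATF6 thus lay further from 0 than simulated by more than the SD, although no gene passed the interaction test there in edgeR.

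At 6 h ER stress genes were higher in 0 mM glucose in the libraries that were kept. With the failed library and all of replicate 2 left out, 13 of 20 ER chaperones rose in each of siControl, siATF4 and siATF6 cells (adjusted p = 4.07e-05, 8.67e-06 and 0.000624 with an estimated correlation), for example HSPA5 (2.45, 2.81 and 1.69) and DNAJB11 (1.82, 1.85 and 1.17). Of 19 degradation and signalling genes 10, 10 and 5 rose (adjusted p = 1e-05, 3.31e-06 and 0.000224 with an estimated correlation), HERPUD1 at 3.32, 3.52 and 2.34. Of 25 translocation genes 9, 10 and 9 rose (adjusted p = 0.00202, 0.000355 and 0.00154 with an estimated correlation), such as the COPII coat gene SEC24D (1.88, 2.36 and 1.93). Of 20 stress regulators 6, 1 and 3 rose (adjusted p = 0.00521, 0.141 and 0.0316 with an estimated correlation), DDIT3 in all of them (3.65, 3.29 and 2.63). Amino acid synthesis genes gave 1, 0 and 0 of 15 up, MTHFD2 in siControl at 0.53 (adjusted p = 0.168, 0.714 and 0.757 with an estimated correlation). OGA, which removes O-GlcNAc from proteins, fell (-1.73, -1.80 and -1.70) while GFPT1 rose (1.47, 1.41 and 1.15).

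Other genes with large 6 h changes in siControl were HSPA6 (5.36), the ER co-chaperone DNAJB9 (3.15), CRELD2 (3.11) and ZNF165 (2.83) up, and LRFN1 (-1.94), P2RY11 (-1.65), RHOV (-1.53), PAQR4 (-1.48) and GRB7 (-1.48) down. A share of 50.0% of the exon length of P2RY11, 41.5% of PAQR4 and 20.3% of LRFN1 belongs also to other genes. The counts were 554 (296 up, 258 down), 226 (170 up, 56 down; 1 library in 0 mM glucose) and 313 (163 up, 150 down). With replicate 2 kept, edgeR called 0 in each siRNA (160, 1024 and 173 at an unadjusted p under 0.05; 2, 1 and 2 in DESeq2), so these changes rest on leaving those libraries out. Without 1 further library siControl gave 273 and 146 (25 mM, replicates 1 and 3) and 278 and 263 (0 mM), siATF4 118 and 84 (25 mM, replicates 1 and 3), and siATF6 122 and 96 (25 mM) and 67 and 158 (0 mM). Only the libraries compared gave 138, 119 and 18, DESeq2 951, 478 and 671, no filter 189 in siATF6, the transfection as a block 88 in siATF4, and the replicate block 1292, 434 and 846.

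The 6 h knockdown comparisons keep replicate 2 and leave out the failed library. With siATF6 in 25 mM glucose SYT11 (-2.34), NKAIN4 (-2.05), SLC4A8 (-2.04), ZNF365 (-1.93) and CDH4 (-1.67) were lower. Higher were CST1 (1.70), PLSCR4 (1.04), NFKB2 (0.91), GEMIN5 (0.88), MBNL1 (0.87) and IPPK (0.79), among 173 genes (36 up, 137 down). In 0 mM glucose SLC4A8 (-2.31), MAP2 (-1.84), SYT11 (-1.79), SDK1 (-1.66) and CDH4 (-1.45) were lower. Higher were CST1 (1.85), PLSCR4 (1.21), RMI2 (1.09), LMNB1 (1.07), EVA1C (1.00) and IPPK (0.94), among 133 genes (39 up, 94 down; 28 up and 127 down with upper-quartile factors). With replicate 2 left out as well, 42 (3 up, 39 down) and 57 (8 up, 49 down) passed. In 0 mM glucose these included lower DNAJB11 (-0.63), CRELD2 (-1.30) and HERPUD1 (-0.76). Without 1 library the 42 became 4 and 3 (siControl replicates 1 and 3) and 15 and 3 (siATF6 replicates 1 and 3), and the 57 became 14 and 11 (siControl) and 25 and 3 (siATF6). Leaving out 1 library moved the 173 to 60 and 65 (siControl replicates 2 and 3) and 67 and 81 (siATF6 replicates 2 and 3), and the 133 to 72 and 59 (siControl replicates 2 and 3) and 58 (siATF6 replicate 3). Only the libraries compared gave 2 and 0 (edgeR), DESeq2 387 and 390, no filter 105 and 68, and the replicate block 785 and 780 (330 and 371 without replicate 2).

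For siATF4 at 6 h, 3 genes passed in 25 mM glucose (0 up, 3 down), among them SEC61A2 (-0.67) and MACROH2A1 (-0.51), and 8 in 0 mM, with CMTM3 (1.08) and IPPK (0.82) higher and UNKL (-0.99), SH3BP2 (-0.89), RAB22A (-0.77), GPX8 (-0.74) and MACROH2A1 (-0.68) lower. Amino acid synthesis genes were lower in 25 mM glucose with 8 of 15 passing adjusted over the list alone and 0 over all genes (adjusted p = 2.16e-16; adjusted p = 0.155 with an estimated correlation). With replicate 2 left out edgeR gave 0 in both (344 and 494 at an unadjusted p under 0.05; 2 and 20 in DESeq2; 0 and 2 with the replicate block), and 1 gene passed without siATF4, 25 mM, replicate 1 or siControl, 0 mM, replicate 1. Leaving out 1 library moved the 3 to 5, 0 and 0 (siControl replicates 1 to 3) and to 0 and 0 (siATF4 replicates 2 and 3), and the 8 to 4 (siControl replicate 3) and to 2 and 0 (siATF4 replicates 1 and 2). Only the libraries compared gave 0 and 0, DESeq2 18 and 29, the replicate block 39 and 27, no filter 0 and 3, and with upper-quartile factors the 3 were 1 up and 2 down.

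At 6 h no gene passed the interaction tests with siATF4, with siATF6 or between them in edgeR, either with replicate 2 (132, 81 and 137 at an unadjusted p under 0.05; 1, 2 and 2 in DESeq2) or without it (145, 171 and 172; 2, 5 and 5 in DESeq2). Without replicate 2, 1 gene passed for siATF4 when siControl, 0 mM, replicate 1 or siATF4, 25 mM, replicate 1 was left out. The same held for siATF6 without siControl, 0 mM, replicate 1, and between the knockdowns without siATF4, 25 mM, replicate 1 or siATF6, 0 mM, replicate 1. Without replicate 2, ER-associated degradation genes responded less in siATF6 than in siControl as a list (adjusted p = 0.0474 with an estimated correlation, HERPUD1 -0.98 with adjusted p = 0.86). Both this list and the ER chaperones responded more in siATF4 than in siATF6. The siATF4 side holds 1 library in 0 mM glucose there, so this difference between the knockdowns rests on a single culture.

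In siControl the log2 response grew from 6 to 16 h. ATF4 (n = 3) fell from 341 to 158 CPM in 25 mM and rose from 355 to 460 in 0 mM. With the doubtful 6 h libraries left out, 12 of 20 stress regulators (18 adjusted over the list alone), 10 of 15 amino acid synthesis genes, 5 of 11 transporters and 9 of 18 tRNA synthetases had a higher log2 response at 16 h (adjusted p = 0.000208, 0.000155, 0.000208 and 0.0197 with an estimated correlation), such as CEBPG (1.14), MTHFD2 (1.56), SLC1A4 (2.15) and GARS1 (1.49). ER chaperones (11 of 20) and the degradation list (6 of 19) were also higher, with HSPA5 at 1.43 and XBP1 at 1.36 (adjusted p = 0.0411 for both with an estimated correlation). Of 22 S phase genes 18 were lower, such as MCM3 (-1.72; adjusted p = 0.000155 with an estimated correlation). The largest differences were KLHDC7B (4.56), ADM2 (4.17), PRDM16 (4.04), CHAC1 (3.67), RPS6KA2 (3.51) and LAMP3 (3.47). Lower were NCALD (-3.08), CLDN2 (-2.97), FAM111B (-2.79), SYT12 (-2.60), MCM10 (-2.25) and CLSPN (-2.19). The count was 883 (424 up, 459 down), 1641 (779 up, 862 down) with replicate 2 kept, and 25 (10 up, 15 down) with all 36 libraries. Without 1 library the 883 became 461 and 506 (siControl, 25 mM, 6 h, replicates 1 and 3) and 541 (0 mM, 6 h, replicate 3), and the 1641 became 1090 and 914 (6 h, replicate 2, 25 and 0 mM). For the 883 DESeq2 gave 1503 and the replicate block 2094.

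The planned fit of all 36 libraries gave these counts with its full alternatives. Deprivation at 6 h gave 0 genes in siControl and siATF6 in edgeR (38 and 47 at an unadjusted p under 0.05; 40 and 45 in DESeq2) and 2212 in siATF4 (2176 up, 36 down), and 0 without the failed library or with the transfection as a block (1673 at an unadjusted p under 0.05 with the block). In siATF4 1001, 1192 and 1161 passed without siATF4, 25 mM, replicates 1 to 3. SiATF4 against siControl in 0 mM glucose gave 2167 at 6 h (2134 up, 33 down) and 8 without the failed library, and 833, 1382 and 1237 without siControl replicates 1 to 3 and 3331 without siATF4 replicate 1. In 25 mM glucose it gave 0 (118; 54 in DESeq2). At 6 h siATF6 gave 5 (0 up, 5 down) and 2 (0 up, 2 down), and without any 1 of the libraries compared 1 to 2 and 1; the replicate block gave 14 and 10 (13 and 37 at 16 h). The 531, 325 and 831 genes of deprivation at 16 h became 273, 217 and 238 (25 mM, replicates 1 to 3) and 224, 299 and 294 (0 mM) in siControl. They became 88, 206 and 93 (25 mM) and 155 and 117 (0 mM, replicates 1 and 3) in siATF4, and 377, 415 and 389 (25 mM) and 446, 440 and 426 (0 mM) in siATF6. DESeq2 on all 36 gave 1641, 1545 and 2125, and the transfection as a block 224, 67 and 407 (1 for the time interaction). The 14 genes of siATF4 in 0 mM glucose at 16 h became 7, 4 and 3 (siControl replicates 1 to 3) and 7, 7 and 1 (siATF4). The 10 of siATF6 became 6 and 5 (siControl replicates 2 and 3) and 5, 4 and 3 (siATF6), and the 4 of siATF6 in 25 mM became 2 without siATF6 replicate 2. Interactions at 6 h gave 1 (siATF4), 0 (siATF6; 36 at an unadjusted p under 0.05; 35 in DESeq2) and 0 (between the knockdowns; 2341; 538 in DESeq2). Leaving out siATF4, 0 mM, replicate 1 or 2 gave 2028 or 1975 for the first and 2014 or 1950 for the third. The 1 gene of the first became 0 without siControl, 25 mM, replicates 1 to 3, siControl, 0 mM, replicate 2, siATF4, 25 mM, replicates 1 to 3 or the failed library. The 25 genes of the time interaction became 14, 10 and 15 (25 mM, 6 h, replicates 1 to 3), 16 and 12 (0 mM, 6 h, replicates 1 and 2), 11, 10 and 12 (25 mM, 16 h) and 10, 12 and 11 (0 mM, 16 h).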

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

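The tests of label exchange, of DNA reads and of genomic span in this part, and the splits in the sets of 18 and 35 libraries, were chosen after the result was seen. The splits of all 36 libraries and the depth test were set before it. The first DNA test, by medians, had a lower-class median of 0, so a ratio of pooled counts replaced it.

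The response to deprivation differed between groups in the interaction tests. For siATF4 at 16 h, in the 18 libraries of that time, 31 genes differed from siControl, with DKK1 (1.39) and RECQL4 (0.83) higher and ADM2 (-2.68), KLHDC7B (-2.61), PRDM16 (-2.41), ULBP1 (-2.39), PTPDC1 (-1.64) and SLC1A4 (-1.47) lower. The lists that differed were stress regulators (adjusted p = 0.000472 with an estimated correlation), amino acid synthesis (2.06e-05) and amino acid transporters (0.000324). Between siATF4 and siATF6 64 genes differed, with the same lists at 0.000159, 5.43e-05 and 0.000805 and ER chaperones at 0.00436, and ER chaperones differed between siATF6 and siControl (0.0162). At 6 h, with the failed library and replicate 2 left out, the latter for the direction of its deprivation response, the degradation list differed between siATF6 and siControl (0.0474) and between the knockdowns (0.0129), and ER chaperones between the knockdowns (0.0135). The planned fit gave 1 gene for siATF4 at 6 h.

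Of 25 splits for each interaction, 6 gave at least the 31 genes of siATF4 at 16 h (highest other 1605) and 3 at least the 64 between the knockdowns (highest other 80), so chance is not excluded by these splits. The splits take no account of replicate number or shared transfection; with the transfection as a block the 31 and 64 became 12 and 21, and with the replicate number 143 and 218. The transfection block rests on siATF4 wells whose deviations, in replicates 2 and 3, correlated at -0.318 and -0.0836. Those of 25 mM, replicate 2, with 0 mM, replicate 3, gave 0.53, so the pairs are uncertain. The 1605 and 80 arose from exchanges of 4 libraries in 25 mM. For siATF6 at 16 h 25 splits reached the real 0 in edgeR (412 genes at an unadjusted p under 0.05; 16 in DESeq2; 2 with the replicate block; highest other 1). In the planned fit the splits that reached the real count numbered 7 (siATF4 at 6 h; real 1, highest other 967), 25 (siATF6 at 6 h; real 0, highest other 48), 25 (between knockdowns at 6 h; real 0, highest other 1092) and 25 in each interaction at 16 h (real 0; highest other 1, 0 and 1). In the 35 libraries siATF6 at 6 h gave 25 (real 0, highest other 557).

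The deprivation response in siControl differed between 6 and 16 h for 25 genes with all 36 libraries, 1641 with 35 and 883 with 29. In the last set the lists were stress regulators (adjusted p = 0.000208 with an estimated correlation), amino acid synthesis (0.000155), transporters (0.000208), tRNA synthetases (0.0197), ER chaperones (0.0411), the degradation list (0.0411) and S phase (0.000155). Only 1 of 25 splits, the real one, reached 25 genes (highest other 6) or 1641 genes (highest other 739), but nearly all the others put both times in a group, which adds the difference between times to its spread, so their low counts do not show that chance is excluded. With the transfection as a block the counts were 1, 1782 and 1045 in the sets of 36, 35 and 29, so the 25 genes of the planned fit depend on it. The 1641 comes from a set that keeps replicate 2 of 6 h, which ran against its glucose labels. The split with 739 exchanges the times of all siControl libraries in 0 mM glucose, which brings in differences between the times.

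For comparisons of 2 groups the 10 splits are too few for a share under 0.05. With the 16 h libraries alone, real and highest other counts were 5229 and 0, 5233 and 748, and 6033 and 0 for deprivation in siControl, siATF4 and siATF6, 8 and 0, and 2235 and 0 for siATF4 in 25 and 0 mM glucose, and 135 and 0, and 725 and 1 for siATF6. The 748 genes came when both replicate 2 libraries of siATF4 changed places. In the planned fit they were 531 and 0, 325 and 1, and 831 and 0 for deprivation at 16 h, 0 and 1, and 14 and 0 for siATF4, and 4 and 0, and 10 and 0 for siATF6. At 6 h they were 0 and 8, 2212 and 2409, and 0 and 0 for deprivation, 0 and 0, and 2167 and 2866 for siATF4, and 5 and 0, and 2 and 0 for siATF6. Of the splits 7 reached the 2212 and 9 the 2167, which points to the failed library, without which the real counts were 0 and 8. In the 35 libraries siControl and siATF6 deprivation at 6 h gave 0 and 313, and 0 and 0, siATF4 in 25 mM 3 and 0, and siATF6 173 and 0, and 133 and 421. The 421 arose when the siATF6 replicate 2 and siControl replicate 3 libraries in 0 mM glucose changed places, and 2 of 10 splits reached the 133.

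At 6 h the libraries labelled replicate 2 in siControl and siATF6 ran against their glucose labels. An exchange of siRNA labels is argued against by ATF6, whose highest CPM in the replicate 2 libraries labelled siATF6 was 0.193 of the lowest in those labelled siControl. An exchange of the glucose labels within each pair stays open and was not tested, since the correlations with the 16 h change, -0.639 at the higher, are what raised it. The positions of both libraries of each pair and the split of siControl at 6 h with 313 genes, which exchanges them, restate that observation. No library was relabelled, and the design gives no biological explanation, so none was tested.

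The library labelled siATF4, 0 mM glucose, 6 h, replicate 3 had few counts and resembled no other. Low depth alone is argued against, since replicate 1 of the same group thinned to the same total still correlated at 0.964 with another library. Whether DNA or other unselected reads are the source stays open. Genes above 10 CPM elsewhere had 1.22 times the pooled count per kb of exon of those under 0.1 CPM. The other 35 libraries gave at least 2843. The medians per kb, 9.56 and 0, go against such a source. The design gives no biological explanation, and none was tested.

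Genes with a long genomic span were lower at 16 h with siATF6 in 25 and 0 mM glucose and with siATF4 in 0 mM (rank correlations of log2 fold change with span -0.274, -0.251 and -0.363 across 14297 genes, which are not independent). With siATF4 in 25 mM the value was -0.167, -0.0734 with exon length and expression held and -0.113 with GC content held as well, and no cause was tested. For siATF6 exon length and GC content as the whole cause are argued against, because the correlation was -0.175 or lower with exon length and expression held and -0.188 or lower with GC content held as well, and -0.208 or lower without any 1 library. For siATF4 in 0 mM a single library as the whole cause is argued against (-0.178 without replicate 3), but exon length (-0.18) and GC content (-0.104) cannot be told apart from span, since exon length with span held gave a stronger -0.41, GC content alone 0.286, and without that replicate the values held for them rose to -0.0877 and -0.0767. Lower transcription of long genes after knockdown may be a biological explanation, which the design cannot separate from other effects of an siRNA, and it was not tested.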

How the results depend on the processing

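Alternatives were set before the data were examined, except the sets of 35, 29 and 18 libraries and everything repeated in them, which were chosen after the results were seen. Counts are of edgeR unless DESeq2 is named, and only those are listed that moved by over 1.5 times or on or off 0; the number after a 0 in brackets is the count at an unadjusted p under 0.05. The cause of a shift was not tested, except that a fit of only the libraries compared, or without 1 library, has fewer libraries to estimate spread. In the set of 29, the lone siATF4 library in 0 mM glucose at 6 h is assumed to vary like the other groups. Apart from the sets of libraries themselves, the counts of deprivation at 16 h in siControl and siATF6 in the 18 libraries of 16 h kept within 1.5 times of their value in every setting run. They ran from 3869 to 4317 and from 4797 to 5204 without 1 library. The labels share replicate numbers across groups. Their protocol plates each transfected culture in 2 wells, so within an siRNA and time a number can mark a shared transfection, which the labels do not state; between siRNAs nothing shared is named. For the pairing, deviations from the group means of libraries with the same number correlated at a median of 0.37 at 6 h and 0.256 at 16 h, against -0.193 and -0.239 with different numbers, and at over 0.1 in 35 of 40 and 38 of 45 pairs. Every library correlated best with one of its own number at 6 h. At 16 h siATF4, 25 mM, replicate 2, siATF4, 0 mM, replicates 2 and 3, and siATF6, 0 mM, replicate 3 did not. Pairs with the same number and siRNA ran from -0.318 to 0.512. The exceptions held replicate 2 of siControl or siATF6 in 25 mM at 6 h, or siATF4 in 0 mM at 16 h, replicates 2 or 3. Comparisons without these had every pair over 0.1, and the results give the block's count where it moved; for the others it is a hint from the data. The leading fits and the splits take no account of the number.

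In the planned fit of all 36 libraries, these settings moved a count. Deprivation with DESeq2 gave 40 (siControl at 6 h), 45 (siATF6 at 6 h), 1641 (siControl at 16 h), 1545 (siATF4 at 16 h) and 2125 (siATF6 at 16 h). Knockdowns with DESeq2 gave 54 (siATF4 in 25 mM at 6 h), 106 (siATF6 in 25 mM at 6 h), 90 (siATF6 in 0 mM at 6 h), 65 (siATF4 in 25 mM at 16 h), 454 (siATF4 in 0 mM at 16 h), 110 (siATF6 in 25 mM at 16 h) and 179 (siATF6 in 0 mM at 16 h). Interactions with DESeq2 gave 499 (siATF4 at 6 h), 35 (siATF6 at 6 h), 538 (siATF4 against siATF6 at 6 h), 93 (siATF4 at 16 h), 62 (siATF6 at 16 h), 107 (siATF4 against siATF6 at 16 h) and 392 (time). Deprivation without the failed library and replicate 2 of 6 h gave 554 (siControl at 6 h), 226 (siATF4 at 6 h) and 313 (siATF6 at 6 h). Knockdowns without the failed library and replicate 2 of 6 h gave 0 (494; siATF4 in 0 mM at 6 h), 42 (siATF6 in 25 mM at 6 h) and 57 (siATF6 in 0 mM at 6 h). Interactions without the failed library and replicate 2 of 6 h gave 0 (145; siATF4 at 6 h) and 883 (time). Deprivation with the transfection as a block gave 0 (1673; siATF4 at 6 h), 224 (siControl at 16 h), 67 (siATF4 at 16 h) and 407 (siATF6 at 16 h). Interactions with the transfection as a block gave 0 (221; siATF4 at 6 h) and 1 (time). Deprivation with the replicate number as a block gave 986 (siATF4 at 6 h) and 566 (siATF4 at 16 h). Knockdowns with the replicate number as a block gave 876 (siATF4 in 0 mM at 6 h), 14 (siATF6 in 25 mM at 6 h), 10 (siATF6 in 0 mM at 6 h), 54 (siATF4 in 0 mM at 16 h), 13 (siATF6 in 25 mM at 16 h) and 37 (siATF6 in 0 mM at 16 h). Interactions with the replicate number as a block gave 0 (2059; siATF4 at 6 h) and 97 (time). Deprivation with upper-quartile factors gave 4033 (siATF4 at 6 h) and 493 (siATF4 at 16 h). Knockdowns with upper-quartile factors gave 4017 (siATF4 in 0 mM at 6 h), 3 (siATF6 in 25 mM at 6 h) and 24 (siATF4 in 0 mM at 16 h). Interactions with upper-quartile factors gave 2092 (siATF4 at 6 h), 2116 (siATF4 against siATF6 at 6 h) and 64 (time). Deprivation with only the libraries compared gave 0 (129; siATF4 at 6 h), 6926 (siControl at 16 h), 1225 (siATF4 at 16 h) and 7551 (siATF6 at 16 h). Knockdowns with only the libraries compared gave 0 (87; siATF4 in 0 mM at 6 h), 2 (siATF6 in 25 mM at 6 h), 0 (1416; siATF6 in 0 mM at 6 h), 0 (2609; siATF4 in 0 mM at 16 h), 942 (siATF6 in 25 mM at 16 h) and 751 (siATF6 in 0 mM at 16 h). Interactions with only the libraries compared gave 0 (593; siATF4 at 6 h), 6 (siATF4 at 16 h), 7 (siATF6 at 16 h), 11 (siATF4 against siATF6 at 16 h) and 1711 (time). Deprivation without the failed library gave 0 (1024; siATF4 at 6 h). Knockdowns without the failed library gave 3 (siATF4 in 25 mM at 6 h), 8 (siATF4 in 0 mM at 6 h), 173 (siATF6 in 25 mM at 6 h) and 133 (siATF6 in 0 mM at 6 h). Interactions without the failed library gave 0 (132; siATF4 at 6 h) and 1641 (time). Deprivation without the filter on low counts gave 273 (siControl at 16 h), 109 (siATF4 at 16 h) and 401 (siATF6 at 16 h). Knockdowns without the filter on low counts gave 2 (siATF6 in 25 mM at 6 h), 1 (siATF6 in 0 mM at 6 h), 6 (siATF4 in 0 mM at 16 h) and 4 (siATF6 in 0 mM at 16 h). Interactions without the filter on low counts gave 0 (3518; siATF4 at 6 h) and 10 (time). Deprivation with the 16 h libraries alone gave 5229 (siControl at 16 h), 5233 (siATF4 at 16 h) and 6033 (siATF6 at 16 h). Knockdowns with the 16 h libraries alone gave 8 (siATF4 in 25 mM at 16 h), 2235 (siATF4 in 0 mM at 16 h), 135 (siATF6 in 25 mM at 16 h) and 725 (siATF6 in 0 mM at 16 h). Interactions with the 16 h libraries alone gave 31 (siATF4 at 16 h) and 64 (siATF4 against siATF6 at 16 h). Interactions with median-of-ratios factors gave 1 (siATF4 at 16 h). Deprivation without 1 library at a time gave 0 to 3317 (siATF4 at 6 h), 217 to 299 (siControl at 16 h), 88 to 307 (siATF4 at 16 h) and 377 to 446 (siATF6 at 16 h). Knockdowns without 1 library at a time gave 8 to 3331 (siATF4 in 0 mM at 6 h), 1 to 2 (siATF6 in 25 mM at 6 h), 1 to 1 (siATF6 in 0 mM at 6 h), 1 to 7 (siATF4 in 0 mM at 16 h), 2 to 3 (siATF6 in 25 mM at 16 h) and 3 to 8 (siATF6 in 0 mM at 16 h). Interactions without 1 library at a time gave 0 to 2028 (siATF4 at 6 h), 0 to 2014 (siATF4 against siATF6 at 6 h) and 10 to 22 (time).

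In the 35 libraries without the failed one, these settings moved a count. Deprivation with DESeq2 gave 2 (siControl at 6 h), 1 (siATF4 at 6 h) and 2 (siATF6 at 6 h). Knockdowns with DESeq2 gave 18 (siATF4 in 25 mM at 6 h), 29 (siATF4 in 0 mM at 6 h), 387 (siATF6 in 25 mM at 6 h) and 390 (siATF6 in 0 mM at 6 h). Interactions with DESeq2 gave 1 (siATF4 at 6 h), 2 (siATF6 at 6 h) and 2 (siATF4 against siATF6 at 6 h). Deprivation without the failed library and replicate 2 of 6 h gave 554 (siControl at 6 h), 226 (siATF4 at 6 h) and 313 (siATF6 at 6 h). Knockdowns without the failed library and replicate 2 of 6 h gave 0 (344; siATF4 in 25 mM at 6 h), 0 (494; siATF4 in 0 mM at 6 h), 42 (siATF6 in 25 mM at 6 h) and 57 (siATF6 in 0 mM at 6 h). Interactions in the set of 29 gave 883 (time). Knockdowns without the filter on low counts gave 0 (842; siATF4 in 25 mM at 6 h), 3 (siATF4 in 0 mM at 6 h), 105 (siATF6 in 25 mM at 6 h) and 68 (siATF6 in 0 mM at 6 h). Interactions without the filter on low counts gave 973 (time). Knockdowns with the replicate number as a block gave 39 (siATF4 in 25 mM at 6 h), 27 (siATF4 in 0 mM at 6 h), 785 (siATF6 in 25 mM at 6 h) and 780 (siATF6 in 0 mM at 6 h). Interactions with the replicate number as a block gave 3226 (time). Knockdowns with only the libraries compared gave 0 (1003; siATF4 in 25 mM at 6 h), 0 (418; siATF4 in 0 mM at 6 h), 2 (siATF6 in 25 mM at 6 h) and 0 (1416; siATF6 in 0 mM at 6 h). Knockdowns without 1 library at a time gave 0 to 5 (siATF4 in 25 mM at 6 h), 0 to 10 (siATF4 in 0 mM at 6 h), 60 to 136 (siATF6 in 25 mM at 6 h) and 58 to 118 (siATF6 in 0 mM at 6 h). Interactions without 1 library at a time gave 914 to 1802 (time).

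In the set of 29 libraries, these settings moved a count. Deprivation with DESeq2 gave 951 (siControl at 6 h), 478 (siATF4 at 6 h) and 671 (siATF6 at 6 h). Knockdowns with DESeq2 gave 2 (siATF4 in 25 mM at 6 h), 20 (siATF4 in 0 mM at 6 h), 202 (siATF6 in 25 mM at 6 h) and 241 (siATF6 in 0 mM at 6 h). Interactions with DESeq2 gave 2 (siATF4 at 6 h), 5 (siATF6 at 6 h), 5 (siATF4 against siATF6 at 6 h) and 1503 (time). Deprivation with the replicate number as a block gave 1292 (siControl at 6 h), 434 (siATF4 at 6 h) and 846 (siATF6 at 6 h). Knockdowns with the replicate number as a block gave 2 (siATF4 in 0 mM at 6 h), 330 (siATF6 in 25 mM at 6 h) and 371 (siATF6 in 0 mM at 6 h). Interactions with the replicate number as a block gave 2094 (time). Deprivation with only the libraries compared gave 138 (siControl at 6 h), 119 (siATF4 at 6 h) and 18 (siATF6 at 6 h). Knockdowns with only the libraries compared gave 1 (siATF6 in 25 mM at 6 h) and 0 (1418; siATF6 in 0 mM at 6 h). Interactions with only the libraries compared gave 1390 (time). Deprivation with the transfection as a block gave 88 (siATF4 at 6 h). Deprivation without the filter on low counts gave 189 (siATF6 at 6 h). Knockdowns without the filter on low counts gave 1 (siATF4 in 25 mM at 6 h). Deprivation without 1 library at a time gave 146 to 278 (siControl at 6 h), 84 to 118 (siATF4 at 6 h) and 67 to 158 (siATF6 at 6 h). Knockdowns without 1 library at a time gave 0 to 1 (siATF4 in 25 mM at 6 h), 0 to 1 (siATF4 in 0 mM at 6 h), 3 to 15 (siATF6 in 25 mM at 6 h) and 3 to 25 (siATF6 in 0 mM at 6 h). Interactions without 1 library at a time gave 0 to 1 (siATF4 at 6 h), 0 to 1 (siATF6 at 6 h), 0 to 1 (siATF4 against siATF6 at 6 h) and 461 to 843 (time).

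In the 18 libraries of 16 h, these settings moved a count. Deprivation with only the libraries compared gave 1225 (siATF4 at 16 h). Knockdowns with only the libraries compared gave 0 (1513; siATF4 in 25 mM at 16 h), 0 (2609; siATF4 in 0 mM at 16 h) and 942 (siATF6 in 25 mM at 16 h). Interactions with only the libraries compared gave 6 (siATF4 at 16 h), 7 (siATF6 at 16 h) and 11 (siATF4 against siATF6 at 16 h). Knockdowns with DESeq2 gave 165 (siATF4 in 25 mM at 16 h), 3658 (siATF4 in 0 mM at 16 h), 490 (siATF6 in 25 mM at 16 h) and 1542 (siATF6 in 0 mM at 16 h). Interactions with DESeq2 gave 200 (siATF4 at 16 h), 16 (siATF6 at 16 h) and 298 (siATF4 against siATF6 at 16 h). Knockdowns with the replicate number as a block gave 38 (siATF4 in 25 mM at 16 h), 4076 (siATF4 in 0 mM at 16 h), 531 (siATF6 in 25 mM at 16 h) and 1836 (siATF6 in 0 mM at 16 h). Interactions with the replicate number as a block gave 143 (siATF4 at 16 h), 2 (siATF6 at 16 h) and 218 (siATF4 against siATF6 at 16 h). Knockdowns without the filter on low counts gave 1452 (siATF4 in 0 mM at 16 h), 77 (siATF6 in 25 mM at 16 h) and 448 (siATF6 in 0 mM at 16 h). Interactions without the filter on low counts gave 41 (siATF4 against siATF6 at 16 h). Interactions with the transfection as a block gave 12 (siATF4 at 16 h) and 21 (siATF4 against siATF6 at 16 h). Knockdowns without 1 library at a time gave 2 to 10 (siATF4 in 25 mM at 16 h), 543 to 4029 (siATF4 in 0 mM at 16 h), 19 to 92 (siATF6 in 25 mM at 16 h) and 207 to 890 (siATF6 in 0 mM at 16 h). Interactions without 1 library at a time gave 11 to 50 (siATF4 at 16 h), 0 to 1 (siATF6 at 16 h) and 20 to 95 (siATF4 against siATF6 at 16 h).

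For single named genes, the direction and side of the threshold stayed the same in 1039 gene results with median-of-ratios factors (4 lost and 1 gained the threshold), 1027 with upper-quartile factors (8 and 9), 937 with DESeq2 (0 and 107), 984 without the filter (51 and 9), 822 with only the libraries compared (187 and 32), 574 with all 36 libraries (468 lost) and 153 with the 35 (61 and 1). Without 1 library they stayed the same in 6941, lost the threshold in 552 and gained it in 48. With the replicate block 951 stayed the same, 1 lost and 92 gained it, and with the transfection block 537, 33 and 9. The results that turned direction did so with all 36 libraries, among genes SH3BP2 with siATF4 in 0 mM glucose at 6 h (0.16) and OSTC with deprivation in siATF4 at 6 h (-0.00971). Among lists they were amino acid synthesis with deprivation in siControl at 6 h (adjusted p = 0.715) and ER translocation in siATF4 at 6 h (adjusted p = 0.189). List calls stayed the same in 398 cases with all 36 libraries, were lost in 92, gained in 3 and turned direction in 2. They stayed the same in 328 with an estimated correlation and were lost in 167; with fry 375 stayed the same, 106 were lost and 14 gained, and with the replicate block in camera 389, 4 and 23. Among deprivation and interaction lists past the threshold with an estimated correlation in the sets of 29 and 18, the transfection block ended only that of transporters with deprivation in siATF6 at 16 h (adjusted p = 0.0695), and the replicate block, over all comparisons, only that of p53 targets with siATF4 in 25 mM at 16 h (0.0927).

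Medians of genes followed from siControl at 16 h, with all 36 libraries and a threshold of 1, were 1.36 (siATF4) and 2.05 (siATF6) for induced and -1.34 and -1.71 for reduced genes. With a threshold of 2 they were 1.91, 2.79, -1.94 and -2.45. With 0.58 siATF6 gave 1.66 and -1.50. In the 16 h libraries alone induced genes gave 1.11 and 1.42 (threshold 1), 0.79 and 1.01 (0.58) and 1.87 and 2.53 (2), and reduced genes -1.52 for siATF6 (1), -0.82 and -1.09 (0.58) and -1.92 and -2.35 (2). At 6 h the medians were 1.41 and 1.05 for induced and -1.18 and -1.07 for reduced genes. They became 1.01 and 0.77 (0.58), 3.01 and 1.78 (2), and -0.72 and -0.72 (0.58). A higher threshold keeps genes with larger changes by construction. In the sets of 35, 29 and 18 libraries, median-of-ratios and upper-quartile factors shifted the fold change of all genes by no more than -0.05 in any comparison. With all 36 libraries they shifted it by 0.13 and 0.56 for deprivation in siATF4 at 6 h, 0.13 and 0.57 for siATF4 in 0 mM glucose at 6 h, and 0.12 and 0.55, and 0.13 and 0.57, for the 6 h interactions of siATF4 with siControl and with siATF6, comparisons that hold the failed library. Median-of-ratios factors also shifted 4 that do not, deprivation in siATF4 at 16 h (0.09), siATF4 in 0 mM glucose at 16 h (0.09) and the 16 h interactions of siATF4 with siControl (0.08) and siATF6 (0.07). The counts of all these comparisons in the planned fit, and the directions of SH3BP2 and OSTC with all 36 libraries, are to be read against these shifts. Depth limits what the failed library can show at all. Simulated 1.5-fold changes were recovered at 11.9% in the 16 h libraries with only 200 genes changed, which is not the share for the real data.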

Other observations

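All values of the 16 h libraries alone in this part come from a fit chosen after the data were seen. In siControl at 16 h, several lists held single genes that changed while the list as a whole did not pass. Among 7 targets of the glucose-sensing factor MondoA, HBP1 rose (1.24) and PDK4 fell by 1.68 (list adjusted p = 0.818), and among 21 genes of cholesterol synthesis STARD4 (1.65) and HSD17B7 (0.60) rose while 3 members fell (adjusted p = 0.722). Of 6 genes of cholesterol efflux ABCG1 (1.23) and ABCA1 (1.67) rose and LPCAT3 (-0.44) fell (adjusted p = 0.659). The cytokines gave 2 of 19 up, the EGF receptor ligand AREG (1.53) and LIF (0.44; adjusted p = 0.112), and the p53 targets 6 of 18 up, such as GDF15 (1.85) and the cell cycle inhibitor CDKN1A (1.12), with POLH (-0.79) down (adjusted p = 0.113). No member of the 14 NF-kB feedback genes passed in edgeR (adjusted p = 0.857).

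Of 16 heat shock genes 1 rose and 4 fell, such as HSPA4 (-0.57) and HSPA8 (-0.97; adjusted p = 0.366). Of 20 ribosome biogenesis genes 4 fell, such as RRP1B (-0.88; adjusted p = 0.0849), and of 24 nuclear genes of the respiratory chain 2 fell, with SDHA at -0.70 (adjusted p = 0.469), while none of the 13 mitochondrially encoded mRNAs passed (adjusted p = 0.599). Matrix genes gave 3 of 19 up, among them CCN2 (1.17) and CCN1 (0.99), with the integrin subunit ITGB6 (-1.78) down (adjusted p = 0.227). Interferon genes gave IRF7 (1.33) up and 4 of 17 down, such as OAS3 (-1.57; adjusted p = 0.267), and histones H4C8 (1.29) and H2AC6 (0.59) up and H2BC11 (-1.11) down of 13 (adjusted p = 0.818). Among 10 measured markers of non-epithelial cells 4 fell, including COL1A1 (-1.37) and CD14 (-1.39; adjusted p = 0.117).

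TXNIP, a MondoA target that limits glucose uptake, fell at 16 h in siATF4 (-2.73) and siATF6 (-2.42) cells and did not pass in siControl (-0.42, adjusted p = 0.721). The interaction tests in edgeR did not show a difference past the threshold (adjusted p = 0.542 and 1).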
